A study of Homo sapiens with 8 samples.

How the data were processed

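Gene expression was measured in 8 samples of HT144, an established human melanoma cell line, with 1 Illumina bead array per sample. Per the labels, 3 samples carried an empty vector, 2 overexpressed SETDB1 (SETDB1 OE) and 3 overexpressed a mutant form of it (HC/KA-SETDB1 OE). SETDB1 is a histone methyltransferase that lays down a repressive chromatin mark. What HC/KA stands for, and where the construct begins and ends, is not given in the sources used here. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, total RNA was extracted with Trizol and cleaned on columns with DNase treatment, checked on a Bioanalyser and labelled as biotinylated cRNA. All 8 arrays lay on 1 chip, with the arrays of each group at neighbouring positions, so the chip gave no batch to test and position was tied to group by the design.

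The authors deposited a bead intensity per probe and array on a linear scale, not normalized between arrays and without background subtraction, per the file headers and the lowest values. Beside each intensity the authors deposited a detection p-value. How it was computed is not given in the sources used here. It was not strictly ordered by intensity, with Spearman's rho between -0.990 and -0.989 on the 8 arrays. The authors also deposited a processed log2 value per probe and array. Each of its 8 columns had a median of 6.53, and each followed the raw log2 intensity of its own array with a lowest correlation of 0.9996. The median absolute difference from plain quantile-normalized log2 intensities was 0.0143, so its scale and direction were settled from the values: log2, quantile-normalized, not centred on genes and with no background correction visible. It served as an alternative only. No deposited column of sample values was left unused.

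Of the 48107 probes, 5 had a missing cell and were left out, which left 48102. Gene symbols came from the platform annotation of the deposited arrays, brought up to date by gene identifier with a RefSeq gene table of assembly GRCh38.p14. It gave 1 symbol to 30113 probes and several to 8, and it did not list 17986. Of the listed probes, 30074 matched the gene table. Probes with several symbols or none were not named. Control probes were not used here. Intensities were corrected and normalized with neqc in limma 3.58.1 under R 4.3.3, which took the background from the detection p-values, added an offset of 16 and quantile-normalized the arrays on the log2 scale. A probe was kept with a detection p under 0.05 on at least 2 arrays, which 26689 probes met. A gene was read from its probe of highest mean over the 8 arrays, which gave 13974 genes, of which 3815 had more than 1 passing probe. Tables were read with the data.table package, version 1.17.8, and plots were drawn with matplotlib 3.10.9 under Python 3.11.15.

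Groups were compared on the log2 scale with limma (lmFit, contrasts.fit and eBayes), fitted to all 8 arrays with a term per group, with two-sided tests and Benjamini-Hochberg adjustment over the 13974 genes of each of the 3 comparisons. A gene was called at an adjusted p under 0.05. The gene lists, 29 in number, were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison with at least 5 measured members, which 27 lists had. Camera with an estimated correlation and fry were alternatives. Fry tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. The lists covered the pigment cell lineage, dedifferentiated or invasive melanoma, neural crest, matrix, adhesion, MAPK, TGF-beta, NF-kappaB, interferon, antigen presentation, SETDB1 partners and heterochromatin, ZNF, HOX, clustered protocadherin, cancer-testis, imprinted and histone genes. They also covered both parts of the cell cycle, p53 targets, stress responses, hypoxia and glycolysis, lipid synthesis, oxidative phosphorylation, ribosomal proteins, and markers of fibroblasts, epithelial cells, blood cells and endothelium. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Under that rule SETDB1 and THBS1 were always named. Then came the 10 called genes with the largest rise and the 10 with the largest fall among those whose arrays did not overlap between the groups, then up to 4 members per list with the smallest adjusted p. A gene named in a comparison may be quoted in the other 2. Where a gene's chosen probe was not detected on any array of a group, its fold is a bound, given as at least N-fold: the brighter group's mean was set against the mean, over the arrays of the dim group, of the higher of the gene's own value and the lowest value among detected probes.

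On simulated data with the real spread and 100 genes changed at each size, a log2 change of 1 was recovered for 49% of genes in SETDB1 OE vs empty vector, 64% in HC/KA-SETDB1 OE vs empty vector and 38% in SETDB1 OE vs HC/KA-SETDB1 OE. For a log2 change of 2 the recovered shares were 100%, 100% and 99%. Of the simulated calls 5.70%, 4.65% and 2.84% were false. The number of arrays limits the precision.

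Replicate numbers recur across the groups. Over the 13974 genes, deviations from the group means of same-numbered empty vector and HC/KA-SETDB1 OE arrays correlated at 0.46, 0.19 and 0.15. All were over 0.1, so these numbers were taken to pair the arrays. Those of SETDB1 OE and empty vector, at 0.15 and 0.12, were over 0.1 as well, and those of SETDB1 OE and HC/KA-SETDB1 OE were 0.12 and 0.03. The main fit, fixed before, held no term for this pairing. This pairing comes from the values, not from a statement in the labels, and HC/KA-SETDB1 OE replicate 2 correlated more with empty vector replicate 3 (0.36) than with its own number. A fit with the replicate number as a block was an alternative. Further alternatives were quantile normalization without background correction, normexp with an offset of 50, scaling to the 75th percentile, the authors' value table, no detection filter or a stricter one, the mean of a gene's probes or every probe, a fit of only the 2 groups compared, array weights, an intensity trend with robust eBayes, and leaving out each array in turn. For the 2 comparisons that share the empty vector arrays, 100 draws of unchanged groups against the same arrays gave the chance values. The draws were independent between genes, so their ranges leave out variation that arrays share across genes.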

Results

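Transcript levels were compared across 8 arrays of HT144 melanoma cells: 3 empty vector, 2 SETDB1 OE and 3 HC/KA-SETDB1 OE. The median intensity lay between 89.0 and 94.4 per array, and between 44.6% and 45.7% of the probes were detected, so the arrays were alike in depth by these measures. The background SD estimated for the correction was not alike. It was 25.9 for empty vector replicate 2 and 13.7 for SETDB1 OE replicate 1, and between 4.58 and 6.77 for the other arrays. Over all genes, arrays of a group correlated at 0.979 to 0.988 for empty vector, 0.984 for the SETDB1 OE pair and 0.961 to 0.978 for HC/KA-SETDB1 OE. HC/KA-SETDB1 OE replicate 2 correlated most with empty vector replicate 3 (r = 0.987), above its correlation with either array of its own group. On the first principal component, which held 39.2% of the variance, it lay at 8.43, while the other HC/KA-SETDB1 OE arrays lay at 36.5 and 40.9 and the empty vector arrays between -12.0 and -0.48.

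The series compared arrays labelled SETDB1 OE with empty vector arrays and with arrays labelled HC/KA-SETDB1 OE. SETDB1 was read by a single passing probe, ILMN_1718207. Its normalized log2 intensity was 8.25, 8.19 and 8.04 in the empty vector arrays, 8.0 and 7.66 in the arrays labelled SETDB1 OE, and 8.32, 8.42 and 9.0 in HC/KA-SETDB1 OE. The log2 fold change was -0.33 (SE 0.24, limma adjusted p = 0.692) for SETDB1 OE vs empty vector and 0.42 (SE 0.22, adjusted p = 0.463) for the mutant. Between SETDB1 OE and HC/KA-SETDB1 OE it was -0.75 (SE 0.24, adjusted p = 0.107), or -0.87 with array weights (adjusted p = 0.0475). Thus the arrays labelled SETDB1 OE held less of this signal than empty vector, within the error of the test, and the probe gave no check of that label. Whether it lies inside the transcribed part of the construct is not given in the sources used here, and a probe outside it checks nothing. THBS1, which encodes the secreted matrix glycoprotein thrombospondin 1, rose by a log2 of 3.33 (10-fold, SE 0.28, adjusted p = 0.000537) in the arrays labelled SETDB1 OE. In HC/KA-SETDB1 OE its log2 fold change was -0.19 (SE 0.25, adjusted p = 0.814), and 0.02 without empty vector replicate 2 (adjusted p = 0.989). The direct comparison of SETDB1 OE with HC/KA-SETDB1 OE gave 3.51 for THBS1 (SE 0.28, adjusted p = 0.000311).

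**Figure D1:**
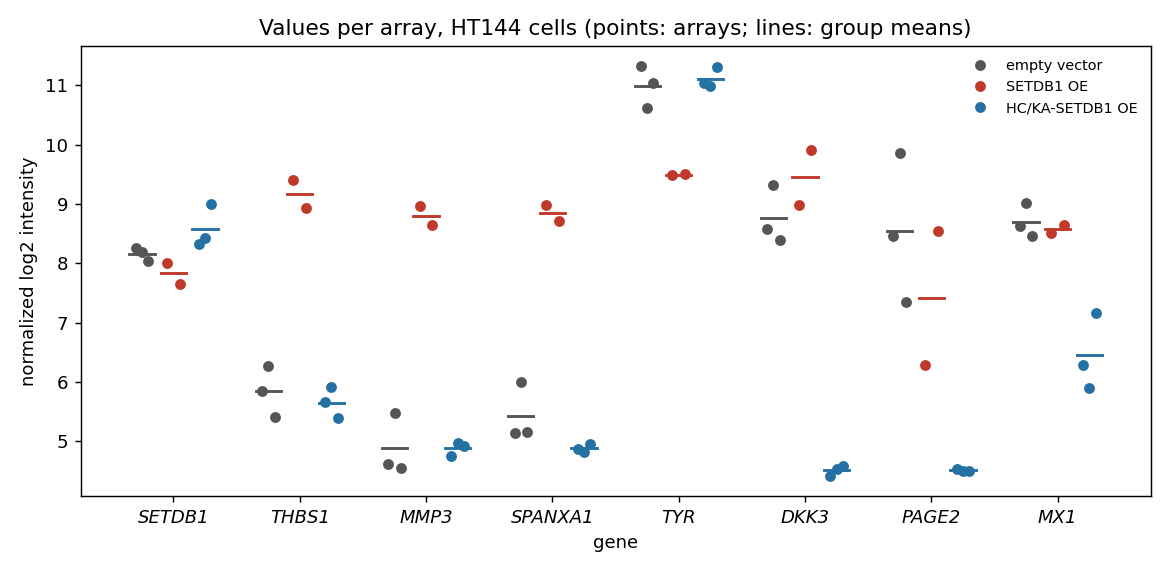
Normalized log2 intensity (vertical axis) of 8 genes in each of the 8 arrays. Points are arrays, coloured by group, and lines are group means. THBS1, MMP3 and SPANXA1 lie higher in both arrays labelled SETDB1 OE than in any other array, TYR lies lower there, and DKK3, PAGE2 and MX1 lie lower in the 3 HC/KA-SETDB1 OE arrays than in any other array.

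In the arrays labelled SETDB1 OE, MMP3, CPA4, THBS1 and 4 SPANX genes were among the called genes with the largest rises against empty vector. MMP3, a secreted matrix metalloprotease, rose by a log2 of 3.92 (15.1-fold, SE 0.28, n = 2 and 3, adjusted p = 0.000537) and was detected on 1 of the 3 empty vector arrays. The SPANX genes, a family of testis-expressed genes, rose together: SPANXA1 by 3.42 (SE 0.27), SPANXA2 by 3.29 (SE 0.30), SPANXB1 by 3.12 (SE 0.27) and SPANXC by 2.95 (SE 0.25), with adjusted p of 0.000801 for SPANXA2 and 0.000537 for the others. These family members are near-identical, and their probes may read each other's transcripts. SPANXC was detected on 1 of the 3 empty vector arrays. CPA4, a carboxypeptidase, rose by 3.72 (SE 0.59, adjusted p = 0.0390, detected on 1 empty vector array). SCG5, a chaperone of neuroendocrine secretory granules that was not detected on any empty vector array, was at least 7.16-fold higher (adjusted p = 0.000537). The long non-coding RNA UCA1 rose by 2.55 (SE 0.30, adjusted p = 0.00604, detected on 1 empty vector array) and the cytokine receptor gene IL7R by 2.43 (SE 0.24, adjusted p = 0.00115). A second IL7R probe gave 0.59 and did not pass.

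The genes that fell in the arrays labelled SETDB1 OE included TYR, the rate-limiting enzyme of melanin synthesis, by 1.5 on the log2 scale (SE 0.24, adjusted p = 0.0382), and QPRT, an enzyme of NAD synthesis, by 2.17 (SE 0.31, adjusted p = 0.0265). PALM, the beta-tubulin gene TUBB4A and the synaptic vesicle gene SV2A also fell, with log2 fold changes of -1.84, -1.83 and -1.53. The adhesion gene CEACAM1 (-1.76), FAM167B (-1.45), the transcription factor gene HES6 (-1.43) and the chaperone gene HSPA2 (-1.38) made up the rest, with adjusted p between 0.0330 and 0.0495 over these genes. Of the other probes of PALM, 1 was undetected in SETDB1 OE and 1 gave -1.02, and other probes of CEACAM1 and HSPA2 gave between -1.81 and -1.18. None of them passed. In all 28 genes rose and 9 fell, each by at least 2-fold. By chance 698.7 genes would have an unadjusted p under 0.05, and 1513 did. The count of 37 called genes fell to 14, 29 and 15 without empty vector replicates 1, 2 and 3. It fell to 10 and 20 without SETDB1 OE replicates 1 and 2 and to 17 without HC/KA-SETDB1 OE replicate 3, and it rose to 109 and 75 without HC/KA-SETDB1 OE replicates 1 and 2. MMP3, THBS1 and the 4 SPANX genes named here stayed called under all 20 alternatives and SCG5 under the 18 that tested it. Without SETDB1 OE replicate 1 the adjusted p of TYR was 0.470 and that of QPRT 0.328.

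Melanoma state genes moved as groups in the arrays labelled SETDB1 OE. Of 23 measured genes of the dedifferentiated or invasive melanoma list, 3 rose, and 12 rose when adjusted over the list alone. Beside THBS1 these were ANKRD1, a target of the Hippo pathway, by 2.28 (SE 0.20, adjusted p = 0.000675), and TPM1, a tropomyosin gene, by 2.19 (SE 0.28, adjusted p = 0.0108). ANKRD1 was detected on 1 of the 3 empty vector arrays. The list's median log2 fold change was 0.82 (camera adjusted p = 5.87e-13), and adjusted p = 0.0263 with an estimated correlation. Among 24 pigment cell lineage genes, TYR fell and 12 fell when adjusted over the list alone. Their median was -0.80 (camera adjusted p = 9.16e-12), and the call was lost with an estimated correlation (adjusted p = 0.144). PMEL, a structural protein of melanosomes, had -1.92 (SE 0.38, adjusted p = 0.0848), PPARGC1A, a coactivator of mitochondrial genes, -2.14 (SE 0.49, adjusted p = 0.123) and CAPN3 -1.39 (SE 0.35, adjusted p = 0.151). None of 19 measured genes of NF-kappaB and inflammatory cytokines passed over all genes and 10 rose when adjusted over the list alone. The median was 1.10 (camera adjusted p = 4.41e-09), with adjusted p = 0.304 under an estimated correlation. IL6 had 3.15 (SE 0.56, adjusted p = 0.0559) and IL1B 1.85 (SE 0.34, adjusted p = 0.0583), each detected on 1 of the 3 empty vector arrays. CXCL8 had 2.40 (SE 0.55, adjusted p = 0.123) and SOD2 1.21 (SE 0.28, adjusted p = 0.123). The SETDB1 OE arrays were uneven: in replicates 1 and 2, IL6 lay at 9.18 and 6.92 and CXCL8 at 12.98 and 11.16. IL1B (6.89 and 6.60) and SOD2 (10.55 and 10.09) were closer.

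A further 4 lists passed camera in this comparison. Of 50 measured cancer-testis antigens, 5 rose, all of them SPANX genes, and 6 rose when adjusted over the list alone. Their median was 0.26 (camera adjusted p = 1.08e-06; adjusted p = 0.144 with an estimated correlation). In the TGF-beta response, 1 of 19 genes rose, THBS1, and PMEPA1 (1.17, adjusted p = 0.277) and ID1 (0.90, adjusted p = 0.370) did not pass. THBS1 was also the 1 gene that rose when adjusted over the list alone, and the median was 0.34 (camera adjusted p = 0.000362; adjusted p = 0.144 with an estimated correlation). Of 55 histone genes 1 rose, H4C8 (2.19, SE 0.32, adjusted p = 0.0293), and 3 rose when adjusted over the list alone, H2BC12 (1.05, adjusted p = 0.0849) being next. The median was 0.17 (camera adjusted p = 0.000955; adjusted p = 0.679 with an estimated correlation). Of 23 genes of cholesterol and fatty acid synthesis none passed over all genes or adjusted over the list alone, and FDPS and SREBF1 had -0.75 each. The median was -0.21 (camera adjusted p = 0.0316; adjusted p = 0.473 with an estimated correlation). That last call was lost without empty vector replicate 1, empty vector replicate 3 or SETDB1 OE replicate 2 (adjusted p = 0.0515, 0.115 and 0.143) and with scaling to the 75th percentile (adjusted p = 0.149).

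The other 20 lists did not pass in SETDB1 OE vs empty vector. MAPK pathway output came nearest (camera adjusted p = 0.0672; 3 rose and 1 fell when adjusted over the list alone), with FOSL1 at 1.40 (adjusted p = 0.0869) and EPHA2 at 1.20 (adjusted p = 0.123). Cell adhesion and integrins had adjusted p = 0.237, with ITGA9 at -1.43 (adjusted p = 0.0954, the only member to fall when adjusted over the list alone). Thrombospondins and matrix had adjusted p = 0.487. MMP3 and THBS1 rose, 3 of 34 rose when adjusted over the list alone, and MMP1, detected on 2 of the 3 empty vector arrays, had 2.41 (adjusted p = 0.135). Interferon response, HOX and imprinted genes each had adjusted p = 0.487, with HOXB8 at -0.82 (adjusted p = 0.135). Neural crest, SETDB1 partners and heterochromatin, clustered protocadherins, p53 targets, the unfolded protein and integrated stress response and fibroblast markers each had 0.725, with SLC7A11, a cystine transporter detected on 2 of the 3 empty vector arrays, at 1.01 (adjusted p = 0.102). Antigen presentation had 0.989, ZNF genes 0.873, and the cell cycle lists 0.738 (G1 and S phase, with RRM2 at 1.17, adjusted p = 0.123) and 0.774 (G2 and M phase). Hypoxia and glycolysis had 0.774 (ALDOC -0.97, adjusted p = 0.123), oxidative phosphorylation 0.611, ribosomal proteins 0.774 and blood and immune cell markers 0.909. Adjusted over the list alone, 1 gene each rose in the G1 and S phase and stress lists and 1 each fell in the HOX and hypoxia lists. No gene of the remaining lists passed. Epithelial and endothelial markers had 4 and 3 measured members, too few to test in any of the 3 comparisons. The median, mean or camera direction differed in sign for the matrix, antigen presentation, SETDB1 partner, G2 and M phase and hypoxia lists. For the matrix list the median was -0.04 and the mean 0.25.

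**Figure D2:**
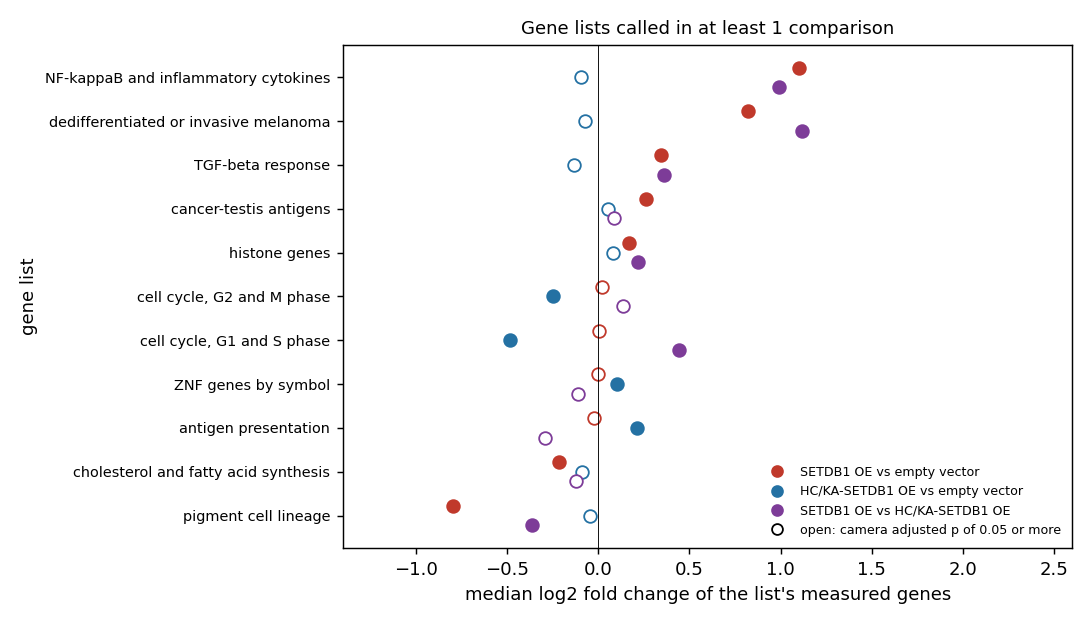
Median log2 fold change of the measured genes (horizontal axis) of each gene list that passed camera in at least 1 of the 3 comparisons (vertical axis). Filled points passed camera at an adjusted p under 0.05 with the preset correlation and open points did not. The dedifferentiated or invasive list lies at 0.82 and the pigment list at -0.80 in SETDB1 OE vs empty vector.

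In HC/KA-SETDB1 OE, DKK3 and PAGE2 had the largest falls against empty vector among the called genes, and ZNF83 had the largest rise. DKK3, a secreted protein of the Dickkopf family, was not detected by its brightest probe on any HC/KA-SETDB1 OE array and was at least 18.4-fold lower by it (n = 3 and 3, adjusted p = 0.000329). A second DKK3 probe, likewise undetected there, was at least 15.1-fold lower, and another, detected on 2 of these arrays, gave -0.07 and did not pass. PAGE2 was undetected in HC/KA-SETDB1 OE, at least 15.9-fold lower (adjusted p = 0.0285), and its near-identical relative PAGE2B fell by 3.19 (SE 0.54, adjusted p = 0.0435), so their signals may be shared. PYCARD, the adaptor of the inflammasome, fell by 2.48 (SE 0.31, adjusted p = 0.0134, detected on 1 of the 3 HC/KA-SETDB1 OE arrays). Among the risers, ZNF83 rose by 2.07 (SE 0.32, adjusted p = 0.0297, detected on 2 of the 3 empty vector arrays) and ZNF415, undetected in empty vector, by at least 3.01-fold (adjusted p = 0.0134). LDOC1 rose by 1.72 (SE 0.21, adjusted p = 0.0134), the cancer-testis gene GAGE12E by 1.68 (SE 0.27, adjusted p = 0.0358) and the translation elongation factor gene EEF1A2 by 1.40 (SE 0.18, adjusted p = 0.0143).

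Further genes that fell in HC/KA-SETDB1 OE were NELL1 (-2.49), MRGPRX3 (-2.44, detected on 2 HC/KA-SETDB1 OE arrays), FSTL5 (undetected there, at least 5.02-fold lower) and the neuronal pentraxin gene NPTX1 (-2.33). The phospholipase gene PLA1A (-2.32, detected on 2 HC/KA-SETDB1 OE arrays) and OCIAD2 (undetected there by its brightest probe, at least 4.65-fold lower) fell too, and adjusted p lay between 0.00670 and 0.0246 for these genes. Second probes of OCIAD2 (detected on 1 HC/KA-SETDB1 OE array) and the riser ADAP1 gave -0.41 and 1.48, and neither passed, nor did a second probe of NPTX1 that was undetected in HC/KA-SETDB1 OE. The transcription factor gene FOXF1 (1.67) and the channel subunit gene CACNA2D4 (1.40), each detected on 2 empty vector arrays, the kinase gene MATK (1.51), ADAP1 (1.42) and SCRN1 (1.14) completed the 10 largest rises, with adjusted p between 0.0235 and 0.0435. In all 11 genes rose and 34 fell, each by at least 2-fold. In addition 1751 genes had an unadjusted p under 0.05 against 698.7 by chance. With the replicate number as a block, 49 rose and 78 fell. The counts of genes that rose and fell were 0 and 2, 0 and 4, and 1 and 19 without empty vector replicates 1, 2 and 3. They were 10 and 20, 128 and 134, and 0 and 6 without HC/KA-SETDB1 OE replicates 1, 2 and 3. DKK3 stayed called under all 20 alternatives. NELL1, LDOC1, EEF1A2 and PYCARD each lost the call in 4 of 20, and PAGE2 in 8 of 20.

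Cell cycle genes stood lower as groups in replicates 1 and 3 of HC/KA-SETDB1 OE and not in replicate 2, and no single member passed. Against the empty vector means, the median of the G1 and S phase list was -0.97 and -0.46 in replicates 1 and 3 and -0.03 in replicate 2, which stood apart from its group. For the G2 and M phase list it was -0.35, -0.37 and 0.15 in the same order. The empty vector arrays themselves lay between -0.15 and 0.18 on both lists. Of 32 genes of the G1 and S phase list, 31 had negative fold changes, the median was -0.48 (camera adjusted p = 4.80e-07) and the call was lost with an estimated correlation (adjusted p = 0.847). RRM2, a ribonucleotide reductase subunit, had -0.90 (adjusted p = 0.172), CDC45, a replication helicase component, -1.35 (adjusted p = 0.230) and thymidine kinase TK1 -0.94 (adjusted p = 0.239). Of 31 genes of the G2 and M phase list, 22 were negative, with a median of -0.25 (camera adjusted p = 0.00703; adjusted p = 0.847 with an estimated correlation), and BIRC5, encoding survivin, had -1.19 (adjusted p = 0.153). ZNF genes stood slightly higher, 249 of 374 being positive, with per-array medians of 0.05, 0.05 and 0.22 in replicates 1, 2 and 3. ZNF83 and ZNF415 rose, over all genes and adjusted over the list alone, ZNF467 had 2.45 (adjusted p = 0.0999, or 0.0333 with the replicate number as a block), and the median was 0.10 (camera adjusted p = 0.0195; adjusted p = 0.847 with an estimated correlation). In antigen presentation, 15 of 18 genes were positive with a median of 0.21 (camera adjusted p = 0.0331; adjusted p = 0.847 with an estimated correlation), and HLA-F had 0.73, HLA-B 0.65 and HLA-DMB 0.63, none passing. Its per-array medians were 0.17, 0.09 and 0.30. No gene of either cell cycle list or of antigen presentation passed when adjusted over the list alone. Leaving out 1 array took the G2 and M phase call to an adjusted p of 0.155 (empty vector replicate 3), 0.0850 (HC/KA-SETDB1 OE replicate 1) and 0.105 (replicate 3). It took the ZNF genes by symbol to 0.0505 and 0.105 (empty vector replicate 3 and HC/KA-SETDB1 OE replicate 3). Antigen presentation went to 0.0910, 0.0661, 0.0539 and 0.141 (empty vector replicates 1 and 3, HC/KA-SETDB1 OE replicates 1 and 3). The G1 and S phase list stayed called, with a median of -0.19 without HC/KA-SETDB1 OE replicate 1. The imprinted genes (median -0.23, camera adjusted p = 0.0534) passed with the replicate number as a block (adjusted p = 0.0373). NDN had -0.89 and CDKN1C -0.66, and none of 20 passed over all genes or adjusted over the list alone.

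Of the other lists in HC/KA-SETDB1 OE vs empty vector, the pigment list had camera adjusted p = 0.0534: BCL2A1, an anti-apoptotic gene, fell by 1.44 (SE 0.20, adjusted p = 0.0226), PMEL had -1.80 (adjusted p = 0.0677, or 0.0301 with the replicate number as a block), and 4 of 24 fell when adjusted over the list alone. Cancer-testis antigens had adjusted p = 0.0912, with PAGE2 and PAGE2B falling and GAGE12E rising, MAGEC1 at 1.43 (adjusted p = 0.0874, or 0.0249 with the block), and 15 rising and 4 falling when adjusted over the list alone. This list holds near-identical GAGE genes, whose probes may read each other's transcripts, so its members are not independent counts. Fibroblast markers had adjusted p = 0.0912, with DCN undetected in HC/KA-SETDB1 OE and at least 2.22-fold lower (adjusted p = 0.0948, or 0.0303 with the block), LUM at -1.42 and, adjusted over the list alone, 2 falling and 1 rising. Ribosomal proteins had 0.0912. In the interferon response (0.532) the antiviral gene MX1 fell by 2.24 (SE 0.30, adjusted p = 0.0158) and the exonuclease gene ISG20 by 1.93 (SE 0.32, adjusted p = 0.0411), and 3 fell when adjusted over the list alone. In oxidative phosphorylation (0.532) COX7B2 fell, undetected in HC/KA-SETDB1 OE and at least 2.92-fold lower (adjusted p = 0.0256). In the matrix list (0.532) VCAN, encoding the proteoglycan versican, fell by 1.71 (SE 0.27, adjusted p = 0.0291), THBS2 had 1.32 (adjusted p = 0.122) and, adjusted over the list alone, 4 rose and 2 fell. The dedifferentiated or invasive list had 0.532, with IGFBP3 at -1.50 (adjusted p = 0.0544, or 0.0325 with the block) and LOX at 0.81 (adjusted p = 0.138), and 1 member each fell and rose when adjusted over the list alone. Neural crest, TGF-beta, p53, stress (PHGDH -0.98, adjusted p = 0.0717) and lipid synthesis lists each had 0.532. SETDB1 partners and heterochromatin, clustered protocadherins (PCDHAC2 0.92, adjusted p = 0.120), histone genes and hypoxia and glycolysis (ALDOC 0.96, adjusted p = 0.0964) each had 0.645. Blood markers had 0.650, HOX genes 0.889, NF-kappaB 0.925, adhesion 0.925 and MAPK output 0.930. Adjusted over the list alone, 1 gene each rose in the MAPK, protocadherin and hypoxia lists and 1 each fell in the stress and oxidative phosphorylation lists. The median, mean or camera direction differed in sign for the MAPK, NF-kappaB, interferon and stress lists.

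In the direct comparison of SETDB1 OE with HC/KA-SETDB1 OE, 290 genes were higher and 316 lower in the arrays labelled SETDB1 OE than in HC/KA-SETDB1 OE. These 606 calls outnumbered the 37 and 45 against empty vector, but without SETDB1 OE replicate 1 there were 41, against 47 for HC/KA-SETDB1 OE vs empty vector, and without SETDB1 OE replicate 2 there were 68 against 45. With a fit of only the 2 groups compared there were 168, against 155 for SETDB1 OE vs empty vector and 40 for HC/KA-SETDB1 OE vs empty vector. DKK3, undetected in the mutant group by its brightest probe, was at least 29.6-fold higher (n = 2 and 3, adjusted p = 0.000184). A second probe, also undetected there, was at least 22-fold higher, and another gave 0.02 and did not pass. NPTX1 was higher by 3.94 (SE 0.38, adjusted p = 0.000854), MMP3 by 3.92 (SE 0.28, adjusted p = 0.000209), SPANXA1 by 3.97 (SE 0.27, adjusted p = 0.000184) and SPANXA2 by 3.94 (SE 0.30, adjusted p = 0.000224). MMP3 and SPANXA2 were detected on 2 of the 3 HC/KA-SETDB1 OE arrays. DKK1, a secreted Wnt antagonist, was higher by 3.77 (SE 0.53, adjusted p = 0.00705), and IL6 by 3.44 (SE 0.56, adjusted p = 0.0114, detected on 1 of the 3 HC/KA-SETDB1 OE arrays). CPA4 was higher by 4.17 (SE 0.59, adjusted p = 0.00705, detected on 1 HC/KA-SETDB1 OE array) and OCIAD2, undetected in the mutant group by its brightest probe, by at least 11.1-fold (adjusted p = 0.00111), with a second probe at 1.38 that did not pass.

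Genes lower in the arrays labelled SETDB1 OE than in HC/KA-SETDB1 OE were led by the zinc finger gene ZNF467 (-3.59, SE 0.59, adjusted p = 0.0120, detected on 1 of the 2 SETDB1 OE arrays) and the secreted ribonuclease gene RNASE1 (-3.40, SE 0.43, adjusted p = 0.00445). They included PYROXD2 (-3.19), MAPT, encoding the microtubule protein tau (-2.90), RAB26 (-2.74), QPRT (-2.49), MACROD1 (-2.48), PPARGC1A (-2.48) and CDK18 (-2.44), and AGT, encoding angiotensinogen, which was undetected in SETDB1 OE and at least 5.58-fold lower. A second probe of CDK18 gave -0.12 and did not pass, nor did a second probe of MAPT that was undetected in SETDB1 OE. At an unadjusted p under 0.05 there were 3086 genes against 698.7 by chance. The counts higher and lower were 170 and 175, and 188 and 190, without empty vector replicates 2 and 3. They were 33 and 8, and 44 and 24, without SETDB1 OE replicates 1 and 2, and 391 and 521, 632 and 712, and 84 and 74, without HC/KA-SETDB1 OE replicates 1, 2 and 3. DKK3, NPTX1, OCIAD2, MMP3, THBS1 and the 4 SPANX genes stayed called under all 20 alternatives, while without SETDB1 OE replicate 1 the adjusted p of ZNF467 was 0.129.

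**Figure D3:**
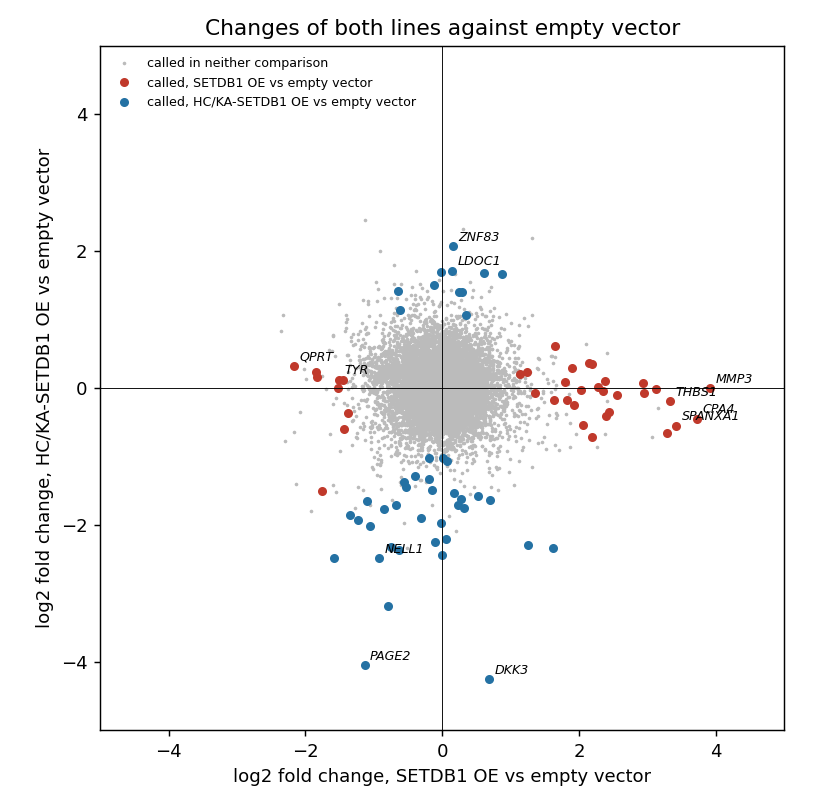
Log2 fold change against empty vector of 13974 genes, SETDB1 OE on the horizontal axis and HC/KA-SETDB1 OE on the vertical axis. Red points are the 37 genes called for SETDB1 OE, blue points the 45 called for HC/KA-SETDB1 OE and grey points genes called in neither. No gene was called in both, and the correlation across genes was -0.018.

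As groups, the melanoma state and inflammatory lists also separated SETDB1 OE from HC/KA-SETDB1 OE. In the dedifferentiated or invasive list 9 of 23 genes were called higher in the arrays labelled SETDB1 OE, among them ANKRD1 (undetected in the mutant group, at least 4.79-fold, adjusted p = 0.000461), TPM1 (2.90, SE 0.28, adjusted p = 0.000854) and IGFBP3 (2.31, SE 0.30, adjusted p = 0.00474). Adjusted over the list alone 12 were higher and 1 lower. Its median was 1.12 (camera adjusted p = 8.03e-08), and it was not called with an estimated correlation (adjusted p = 0.0818). In the NF-kappaB list 4 of 19 genes were higher: IL6, IL1B (1.94, detected on 2 of the 3 HC/KA-SETDB1 OE arrays), the cyclooxygenase gene PTGS2 (1.84) and TNFAIP3 (1.85). In SETDB1 OE replicates 1 and 2, IL6 lay at 9.18 and 6.92 and TNFAIP3 at 8.26 and 6.53. IL1B (6.89 and 6.60) and PTGS2 (9.11 and 9.10) differed less. Adjusted over the list alone 11 were higher and 2 lower, with a median of 0.99 (camera adjusted p = 7.98e-05; adjusted p = 0.632 with an estimated correlation). Of 24 pigment genes 3 were lower, TYR (-1.62, SE 0.24, adjusted p = 0.00772), PPARGC1A and S100B (-1.36), and BCL2A1 had 0.92 (adjusted p = 0.0504). Adjusted over the list alone 7 were lower and 1 higher, with a median of -0.36 (camera adjusted p = 0.00256; adjusted p = 0.632 with an estimated correlation). In the G1 and S phase list 1 of 32 was higher, RRM2 (2.08, SE 0.27, adjusted p = 0.00514), and 2 when adjusted over the list alone, TYMS having 0.94 (adjusted p = 0.0538). The median was 0.44 (camera adjusted p = 0.000128; adjusted p = 0.632 with an estimated correlation), and 0.19 without HC/KA-SETDB1 OE replicate 1 and 0.68 without replicate 2. Per array, this list (cell cycle, G1 and S phase) differed from empty vector by medians of -0.97 and -0.46 in HC/KA-SETDB1 OE replicates 1 and 3, while replicate 2 (-0.03) lay with the SETDB1 OE arrays (0.06 and -0.07). In the TGF-beta response THBS1 and PMEPA1 (2.03, SE 0.38, adjusted p = 0.0193) were higher and 3 of 19 when adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.00312; adjusted p = 0.272 with an estimated correlation). Of 55 histone genes H4C8 was higher (1.83, SE 0.32, adjusted p = 0.0166), also when adjusted over the list alone, and the median was 0.22 (camera adjusted p = 0.0384; adjusted p = 0.632 with an estimated correlation). This call was lost without SETDB1 OE replicate 1 or HC/KA-SETDB1 OE replicates 2 or 3 (adjusted p = 0.198, 0.268 and 0.282).

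The other 21 lists did not pass in this comparison, though several held called genes. ZNF genes (camera adjusted p = 0.0662) had 9 lower and 1 higher, with ZNF415 (undetected in SETDB1 OE, at least 3-fold lower), ZNF83 (-1.91, detected on 1 of the 2 SETDB1 OE arrays) and ZNF609 (-1.22) beside ZNF467, and 4 lower when adjusted over the list alone. Cancer-testis antigens (0.189) had 7 higher, including SPANXB1 (3.13) and SPANXC (3.02, detected on 2 HC/KA-SETDB1 OE arrays), with 9 higher and 3 lower when adjusted over the list alone. In the matrix list (0.841) MMP3, THBS1 and MMP1 (2.6, detected on 2 HC/KA-SETDB1 OE arrays) were higher and THBS2 (-1.99) lower, with 4 higher and 2 lower when adjusted over the list alone. In the adhesion list (0.436) ITGB3 (1.25) and ITGB8 (1.14, detected on 2 HC/KA-SETDB1 OE arrays) were higher and ITGA9 (-1.21) lower, with 4 higher and 3 lower when adjusted over the list alone. SOX9, a neural crest transcription factor, was undetected in the mutant group and at least 1.94-fold higher (list 0.363). MAPK output (0.139) had DUSP5 (0.95) higher and SPRY1 (-1.17) lower, with CCND1 (1.33) and FOSL1 (1.12) at adjusted p = 0.05, not passing, and 4 higher and 1 lower when adjusted over the list alone. MX1 (2.13) was higher in the interferon response (0.138). COX7B2 (undetected in the mutant group, at least 4.76-fold) and NDUFB1 (0.77) were higher and NDUFA7 (-0.79) lower in oxidative phosphorylation (0.955). RPS7 (1.36) and RPL34 (1.68) were higher among ribosomal proteins (0.187). SLC7A11 (undetected in the mutant group, at least 2.42-fold) and TRIB3 (0.98) were higher in the stress list (0.299). GDF15 (-1.29) was lower among p53 targets (0.955), ALDOC (-1.93) in hypoxia and glycolysis (0.916), HOXB8 (-0.91) among HOX genes (0.384) and CD14 (-1.08) among blood markers (0.932). DCN (undetected in the mutant group, at least 2.16-fold) was higher among fibroblast markers (0.384). G2 and M phase had 0.0887, antigen presentation 0.108, clustered protocadherins 0.384, lipid synthesis 0.363, imprinted genes 0.436 and SETDB1 partners and heterochromatin 0.990, with no called gene. Adjusted over the list alone, the interferon response had 2 higher and 1 lower and fibroblast markers 1 each. The same adjustment gave 2 higher and 1 lower in oxidative phosphorylation, 2 higher each for ribosomal proteins and stress, 1 higher in neural crest and 1 lower each for p53 targets, hypoxia, HOX genes and blood markers. The median, mean or camera direction differed in sign for the matrix and oxidative phosphorylation lists. With the replicate number as a block, ITGB8, DUSP5, CD14, NDUFA7, NDUFB1 and HOXB8 lost their calls (limma adjusted p between 0.0510 and 0.0730). CCND1 passed with the block (adjusted p = 0.028).

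No gene was called in both comparisons against empty vector with limma, and the changes in SETDB1 OE and HC/KA-SETDB1 OE were not alike across genes. Of the 606 genes called between SETDB1 OE and HC/KA-SETDB1 OE, 34 of the 37 called for SETDB1 OE and 31 of the 45 called for the mutant were among them, and 541 were called in neither comparison against empty vector. A call in only 1 comparison does not make a gene particular to that group. CEACAM1 had -1.76 in SETDB1 OE and -1.51 in HC/KA-SETDB1 OE, and PYCARD had -1.59 and -2.48. Neither passed in the direct comparison (limma adjusted p over all probes 0.714 and 0.188). Across genes, which are not independent replicates, the log2 fold changes correlated at -0.018, and 51.5% of genes had the same sign. Unchanged groups simulated against the same 3 empty vector arrays gave a mean correlation of 0.447 and a same-sign share of 64.8%, since both comparisons share those arrays. With the same-numbered empty vector and HC/KA-SETDB1 OE arrays correlated as observed, a simulation chosen after the values were seen, these were 0.384 and 62.5%, and the covariance was 0.0220. With the replicate number as a block, the overlap of the SETDB1 OE and HC/KA-SETDB1 OE effects had a correlation of 0.0349. The observed covariance was -0.0027, against 0.0299 in the simulation without pairing. Both simulations drew genes independently, so they do not give the spread of the observed values. Independent lists of these sizes would share 0.0220 genes called higher in both and 0.0219 called lower in both, so the count of 0 carries little information, and the 3 empty vector arrays cannot be split into sets of 2. Genes at an unadjusted p under 0.05 numbered 1513 and 1751.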

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

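No alternative was added after the values were seen. Over the named genes they left direction and side of the threshold the same in 2398 results, lost the call in 540, gained a call in 99 and reversed 1, THBS1 in HC/KA-SETDB1 OE vs empty vector, at 0.0232 (adjusted p = 0.989) without empty vector replicate 2, and between -0.402 and that value with 1 array left out. The gene list calls moved most with the set test: camera with an estimated correlation called 1, 0 and 0 lists in SETDB1 OE vs empty vector, HC/KA-SETDB1 OE vs empty vector and SETDB1 OE vs HC/KA-SETDB1 OE, and fry 3, 0 and 2, where camera with the preset correlation called 7, 4 and 6. In HC/KA-SETDB1 OE vs empty vector the mean of a gene's probes called 8 lists, a fit of only the 2 groups 7 and the intensity trend with robust eBayes 8. For genes higher and lower in SETDB1 OE vs empty vector (28 and 9), the counts were 20 and 5 with quantile normalization without background correction, 27 and 14 with scaling to the 75th percentile, 18 and 5 with the authors' value table, 16 and 0 without the detection filter, 25 and 5 with every probe, 73 and 82 with only the 2 groups, 82 and 58 with array weights and 39 and 24 with the intensity trend. In HC/KA-SETDB1 OE vs empty vector (11 and 34) they were 3 and 15 with quantile normalization, 7 and 24 with normexp, 7 and 41 with scaling, 3 and 14 with the authors' table, 1 and 5 without the filter, 49 and 78 with the replicate block, 41 and 55 with array weights and 26 and 49 with the trend. In SETDB1 OE vs HC/KA-SETDB1 OE (290 and 316) they were 142 and 132 without the filter, 94 and 74 with only the 2 groups, and 512 and 647 with array weights. Array weights also took SETDB1 in that comparison to -0.87 (adjusted p = 0.0475, within a range of 0.0475 to 0.394 over the alternatives). Leaving out the filter adds genes to the adjustment. A fit of only 2 groups takes the spread from the arrays of those groups alone. It raised the calls from 37 to 155 in SETDB1 OE vs empty vector, where the HC/KA-SETDB1 OE arrays, which correlated least within their group, were left out. The calls fell from 45 to 40 in HC/KA-SETDB1 OE vs empty vector and from 606 to 168 in SETDB1 OE vs HC/KA-SETDB1 OE. The cause of these changes and of those under the other alternatives was not tested. Leaving out 1 array gave 10 to 61 genes higher and 0 to 48 lower in SETDB1 OE vs empty vector, 0 to 128 and 2 to 134 in HC/KA-SETDB1 OE vs empty vector, and 33 to 632 and 8 to 712 in SETDB1 OE vs HC/KA-SETDB1 OE. List calls ranged from 1 to 7 in HC/KA-SETDB1 OE vs empty vector and 5 to 10 in SETDB1 OE vs HC/KA-SETDB1 OE, and the correlation of the effects in SETDB1 OE and HC/KA-SETDB1 OE from -0.0711 to 0.0995. Without a SETDB1 OE array the remaining one was assumed to vary like the other groups. In HC/KA-SETDB1 OE vs empty vector the replicate block added PMEL, MAGEC1, IGFBP3, ZNF467, DCN and the imprinted list to the calls and changed no other call of a named gene or list. The imprinted list also passed under 6 further alternatives. For same-numbered SETDB1 OE arrays the correlations were 0.15 and 0.12 with empty vector, also over 0.1, and 0.12 and 0.03 with HC/KA-SETDB1 OE. The block gave 40 and 11 genes in SETDB1 OE vs empty vector and 310 and 355 in SETDB1 OE vs HC/KA-SETDB1 OE. In SETDB1 OE vs empty vector it took the call from TUBB4A (limma adjusted p = 0.0578). There it added PPARGC1A (adjusted p = 0.0167) and MMP1 (adjusted p = 0.0114). Signal over background limits genes near the detection level: median intensities of 89.0 to 94.4 lay close to the background, so folds of genes undetected in a group are bounds.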

Other observations

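The tests of a wrong label, a mixture, shared SPANX signal, the ARMCX1 segment, chip position and the ZNF genes were chosen after the results they address were seen. Intervals in this section come from resampling genes with the arrays held fixed. They treat genes as independent and hold no spread between arrays. Further genes rose in the arrays labelled SETDB1 OE against empty vector, and they were chosen here after their values were seen. HMOX1, encoding the heme-degrading enzyme heme oxygenase, rose by a log2 of 2.38 (SE 0.36, adjusted p = 0.0323), the surface glycoprotein gene CD24 by 2.35 (SE 0.22, adjusted p = 0.000801) and RAB27B, a small GTPase of vesicle secretion, by 2.05 (SE 0.20, adjusted p = 0.00109). In HC/KA-SETDB1 OE the same genes had 0.10, -0.05 and -0.54 and none passed. DKK1, which encodes a Wnt antagonist, had 3.06 against empty vector in the arrays labelled SETDB1 OE (adjusted p = 0.0544), where a second probe, undetected in empty vector, was at least 2.49-fold higher (adjusted p = 0.0150 over all probes), and -0.71 in HC/KA-SETDB1 OE (adjusted p = 0.602), while its relative DKK3 had 0.68 (adjusted p = 0.479) in the former.

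HC/KA-SETDB1 OE replicate 2 lay nearer the empty vector arrays than replicates 1 and 3 did. An array of empty vector RNA under a wrong label would show almost none of the group's change. Over 130 genes called lower without replicate 2, this array showed a median of 46.0% of the change in the other replicates (bootstrap interval 37.8 to 53.5). That was above the share the rule gave for a wrong label but short of the share it asked for to count against one. The rule thus left a wrong label undecided, though a share of almost none was not seen. Of the 130 genes, 12 were undetected in replicates 1 and 3, and 9 of these 12 were undetected in replicate 2 too. An array of empty vector RNA would keep the empty vector signal of such genes. For these genes the values argue against an array of empty vector RNA alone. The share of the change was not uniform over the 130 genes, with quartiles of 18.4 and 75.7. A mixture with empty vector RNA would keep 1 share of the empty vector signal for every gene. The 12 genes undetected in replicates 1 and 3 kept a median of 8.35% (interval 1.97 to 20.2), while the other 118 genes would need 46.5% (interval 41.4 to 59.6). This argues against a mixture as the whole cause. The first rule for a mixture left it undecided, and the comparison with the 118 genes was chosen after that value was seen. What sets this array apart stays open, and no biological explanation was tested.

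Genes called against empty vector clustered on chromosome X, which held 541 of 13974 tested genes: 8 of 45 for HC/KA-SETDB1 OE (1.74 expected; Fisher's exact p = 2.91e-04, adjusted p = 0.00117 over 4 tests) and 5 of 37 for SETDB1 OE (1.43 expected; Fisher's exact p = 0.0134, adjusted p = 0.0267), the latter all SPANX genes, which are not independent of each other. The former were LDOC1 and GAGE12E, higher, and PAGE2, PAGE2B, ARMCX1, FAM133A, NLGN4X and TRO, lower, of which those outside the naming rule were chosen after their values were seen. The near-identical PAGE2 and PAGE2B are not independent of each other either, although Fisher's test counts them so. Gain or loss of a segment would move neighbouring genes, but 61 neighbours had a median of 0.0601 in the direction of the called gene (interval -0.06 to 0.22) and 11 SPANX neighbours 0.0918 (interval 0.01 to 0.14), which argues against it for the cluster as a whole. It stays open at ARMCX1, where 9 of 10 neighbours had the same sign with a median of 0.275 (interval 0.06 to 0.44), at GAGE12E, whose neighbours are mostly near-identical GAGE genes (median 1.08), and for a segment holding only SPANX genes. Signal shared between near-identical SPANX genes and joint regulation cannot be told apart, since the lowest pairwise correlation was 0.923 either way, and a biological difference between the constructs remains untested.

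SETDB1 OE and HC/KA-SETDB1 OE differed from each other at more genes (606) than either did from empty vector (37 and 45), but without SETDB1 OE replicate 1 the order turned (41 against 47 for HC/KA-SETDB1 OE vs empty vector), and without SETDB1 OE replicate 2 it was 68 against 45. With a fit of only the 2 groups compared, the direct comparison had 168 calls, against 155 for SETDB1 OE vs empty vector and 40 for HC/KA-SETDB1 OE vs empty vector. A steady gradient along the chip would move both groups the same way from empty vector. The covariance of both effects against different empty vector arrays was -0.0303 on average and below 0 in 5 of 6 pairs of arrays (range -0.0540 to 0.0163). By the rule for this test a gradient was left open, since the pairs did not agree. A test on the 606 genes was set aside, since they had been selected for the pattern. Each HC/KA-SETDB1 OE array also correlated more with each empty vector array than with each SETDB1 OE array over all genes (18 of 18 comparisons), but this restates the pattern on the same arrays, and 10 splits of the 5 arrays compared are too few for a share under 0.05. Against the same 3 empty vector arrays the covariance over all genes was -0.0027. Unchanged groups, drawn independently per gene, gave 0.0282 to 0.0322, or 0.0201 to 0.0238 with pairing. These ranges leave out variation that arrays share across genes, so they are too narrow to judge the observed value. A steady gradient would raise the covariance. On the first principal component, empty vector arrays (-12.0 to -0.48) lay between SETDB1 OE (-38.6 and -33.9) and HC/KA-SETDB1 OE (8.43 to 40.9). A steady gradient alone would put both groups on the same side of empty vector, which was not the order on this component. That order, however, restates the pattern on the same arrays, so a steady gradient as the only cause stays open, as by the rule. Other effects of position, which was tied to group, and a gradient beside another cause stay open too. So does a biological difference between the constructs, which was not tested apart from them.

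For HC/KA-SETDB1 OE vs empty vector, 1 of the 10 splits of the 6 arrays, the real one, gave 45 called genes, and the highest other gave 0, also among the 4 splits that part all 3 pairs; these splits are too few for a share under 0.05.

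A hypothesis was that the rise of ZNF genes in HC/KA-SETDB1 OE may belong to those of chromosome 19, where many lie in clusters. The 173 genes there had a median of 0.13 and the 201 elsewhere 0.07, a difference of 0.0603 (interval -0.01 to 0.14), which left it open.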
